A study of Mus musculus with 18 samples.

How the data were processed

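Tail genomic DNA of 9 C57BL/6 mice was compared with DNA of 1 reference male of the same colony by 2-colour array comparative genomic hybridisation, which measures the copy number of a sequence as the ratio of the brightness of 2 dyes on a probe. The 9 animals are a father, a mother and their 7 progeny, per the labels, so the family has 1 animal in each parental group and 7 in the progeny group. Each animal was hybridised against the reference on 2 arrays with the dyes Cy3 and Cy5 exchanged, which gives 18 arrays. The 2 arrays of an animal come from the same DNA and were averaged to 1 value per animal. The series title speaks of males exposed to 1 mGy per day of gamma rays for 400 days, while the design text calls the male and female of this family non-irradiated. The exposure of the father is therefore left open here, and no family of an unexposed father was analysed here.

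Each scanner file was made with Agilent Feature Extraction 10.7.1.1, per the file headers, on an array whose probe positions are given on the mouse build mm9. The deposited processed intensity of each channel was background-subtracted, spatially detrended and scaled with 1 linear factor per channel, per the file headers, and the lowess term was 0 on all arrays. The design holds 966371 non-control spots for 950749 distinct probes, of which 950622 lie on the 19 autosomes, 68 on chromosome X, 23 on chromosome Y and 36 on unplaced contigs. The median autosomal probe spacing was 2053 bp and the median probe length 60 bp. The deposited series table gives log2 values of reference over animal on all columns, as found by setting each column beside the scanner values of its array. The correlation over spots was 0.990 to 0.999 and the slope 0.979 to 0.998. Its column medians lay between -0.0047 and 0.013, and the centring and normalization of that table stay unknown.

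The log2 ratio of each spot was taken from the deposited processed intensity, turned to animal over reference from the dye labels, and averaged over the spots of a probe after removal of 114 to 253 outlier spots per array. The autosomal median of each array was set to 0, with no loess or quantile step. No spot was saturated. Median raw signal was 2.54 to 5.83 times local background in red and 3.60 to 7.98 times in green, and 0.015% to 0.864% of spots were not well above background. For arrays, the number of arrays and probes limits the precision.

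Autosomal regions were found with a maximal-interval scan of each animal's dye-swap mean. The score of an interval is the sum of its values over the product of the noise SD and the square root of the number of probes, and the noise SD is a robust SD of differences between neighbouring probes. A call needed a score of 6, at least 3 probes, an absolute mean log2 of 0.25, and the same sign with an absolute mean of 0.125 on each dye orientation. Intervals had at most 2000 probes. Calls of different animals with a reciprocal overlap of 50% of probes formed 1 region. An animal was a carrier of a region when its mean had the sign of the region, reached 50% of the largest called mean and was 4 times its noise error or more. False calls were counted by the same scan of the difference between the 2 orientations, which cancels the DNA of the animal, after each probe's mean over animals was removed. In a test on simulated data, intervals were implanted in those difference profiles. The scan recovered 95.1% of 225 implanted gains of 0.55 over 3 probes, 99.6% of 224 gains of 0.35 over 10 probes and 100% of 225 losses of -0.95 over 3 probes.

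The files used here pair no probe with a gene, and the gene table at hand is on another mouse build (GRCm38.p6), so no gene is named by position. Tests that were planned per gene were run on windows of 10 consecutive autosomal probes instead, of which there were 95054. They used limma 3.58.1 in R 4.3.3 with Benjamini-Hochberg adjustment at 0.05. The family was tested against the reference with an intercept over the 9 animals and an absolute log2 of 0.25, and 7 progeny were tested against 2 parents. The ratio against 0 leaves out the spread between reference animals, since there was 1. On simulated windows the family test recovered 99% and the progeny test 98% of 100 implanted shifts of 0.3, with 0 and 7 false calls. The shifts were added to all 9 animals for the family test and to all 7 progeny for the progeny test. Recovery of a change in 1 animal was not simulated. The planned test of gene lists in called regions, the named gene lists and the sex chromosome genes were not run for the same reason. Calls per animal in progeny and parents were compared with an exact two-sided permutation test over 36 splits, and noise with the animal in Cy5 and in Cy3 with an exact two-sided paired permutation test. Shares of carriers among progeny have exact (Clopper-Pearson) 95% intervals. Scans were written in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and numba 0.67.0.

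The rule for named regions, fixed before the data were examined, takes the 10 progeny regions with no carrier parent of highest score, the 10 other regions of highest score and the 3 longest others. Further regions of 10 or more probes were named after their values were seen. Alternatives fixed before the data were examined were normexp background correction with offset 50 on median signals (the files used here hold no mean signals), centring on all probes, removal of dim probes, subtraction of a running median of 501 probes, the series table, each dye orientation alone, other scan thresholds, other carrier thresholds, a median over probes, leaving out each animal in turn, and scan day as a random block. Alternatives added after the data were seen were a minimum of 10 probes, a median rule for calls, windows of 5 and 20 probes, leaving out progeny 3 and 4, and leaving out tiles of the slide, 250 position units wide, whose SD exceeded 2 times the median tile SD of the array. A named region counted as unchanged when its mean moved by less than its SD over probes. After the values were seen, this was tightened to need an absolute mean of at least 0.125 too, because regions of 3 probes with a large SD had passed at means near 0. The arrays were scanned on 5 days, and both parents were scanned on a day of their own.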

Results

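The family comprised a father, a mother and 7 progeny, each compared with 1 reference male on 2 arrays of opposite dye orientation. All ratios are log2 of animal over reference, positions are on mm9, and the spread given for a single animal is over the probes of a region, since an animal is 1 replicate. The noise SD of the dye-swap mean was 0.105 in the father and 0.114 in the mother. It was 0.102, 0.111, 0.153, 0.139, 0.109, 0.109 and 0.096 in progeny 1 to 7, so progeny 3 and 4, both scanned on day 3, were the noisiest. Single arrays had a noise SD of 0.196 ± 0.024 (SD, n = 9) with the animal in Cy5 and 0.204 ± 0.022 (SD, n = 9) with the animal in Cy3. This difference was within the spread between animals (exact two-sided paired permutation p = 0.266 over 512 sign assignments, lower in Cy5 in 6 of 9 animals).

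The ratios on the sex chromosomes checked the labels and the response of the arrays. Over 68 probes of chromosome X the father stood at 0.03 ± 0.14 (SD over probes) and the mother at 0.90 ± 0.15. Over 23 probes of chromosome Y the father stood at -0.02 ± 0.10 and the mother at -2.39 ± 1.21. The labels do not give the sex of the progeny. Progeny 5, 6 and 7 had chromosome X means of 0.98, 0.96 and 0.95 and chromosome Y means of -3.23, -2.65 and -2.91. Progeny 1 to 4 had chromosome X means between -0.0007 and 0.038 and chromosome Y means between -0.005 and 0.029. With normexp background correction the mother's chromosome X mean was 0.65 and the chromosome Y mean -0.60. Progeny 5, 6 and 7 then had chromosome X means of 0.74, 0.71 and 0.81 and chromosome Y means of -0.73, -0.61 and -0.83. No whole autosome was shifted, since the mean over an autosome lay between -0.0087 and 0.0026 in every animal.

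**Figure D1:**
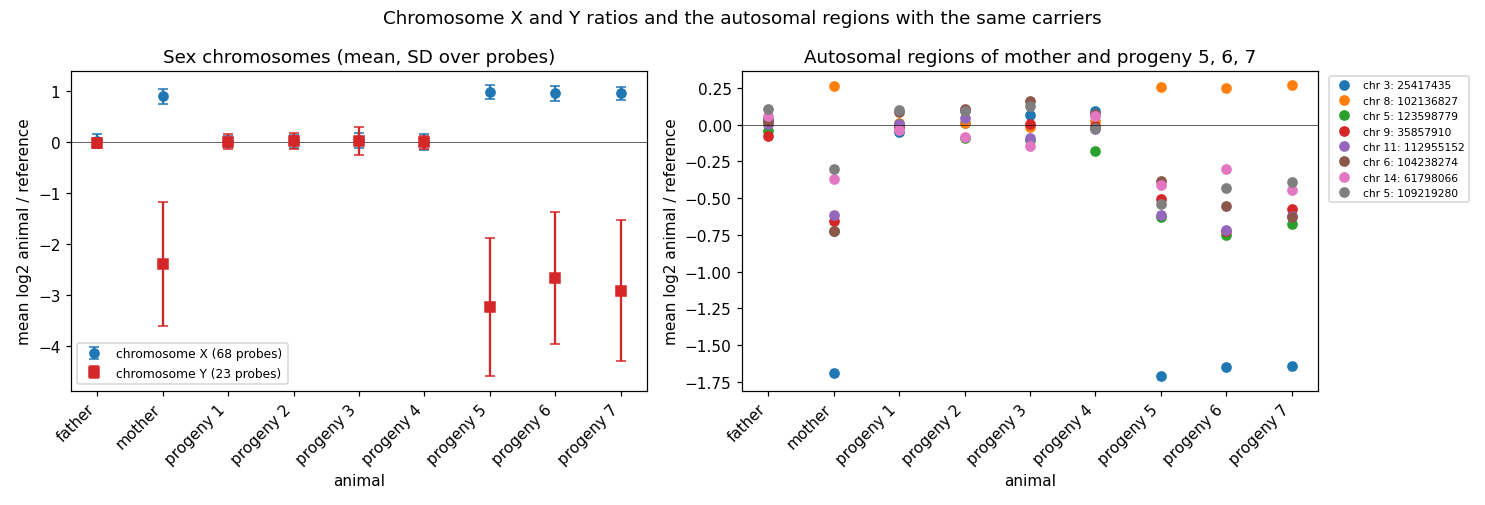
Left, mean log2 ratio of each animal to the reference on chromosome X (circles) and chromosome Y (squares), with bars for the SD over probes. Right, mean log2 ratio of each animal at 8 autosomal regions, where the mother and progeny 5, 6 and 7 stand apart from the other 5 animals, as they do on the sex chromosomes.

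The first comparison asked which autosomal sequences of the family differ in copy number from the reference. The clearest difference was a gain on chromosome 4 at 101110482 to 101270535, 160.1 kb covered by 74 probes. It stood at 0.55 ± 0.10 (SD over probes) in the father and 0.57 in the mother. Progeny 3, 4 and 6 carried it at 0.54 ± 0.02 (SD, n = 3), and the other 4 progeny stood at -0.009 ± 0.002 (SD, n = 4). Carriers were thus 3 of 7 progeny (exact 95% interval 9.90% to 81.6%). On both orientations the father's mean was 0.55.

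Regions carried by all 9 animals numbered 2, but 7 at an absolute log2 of 0.4 and 1 with a stricter carrier threshold. A loss on chromosome 10 at 33897213 to 33933441, 36.2 kb with 19 probes, had a mean of -0.61 ± 0.02 (SD, n = 9), and the animals ranged from -0.65 to -0.60. A shallower loss on chromosome 14 at 53428774 to 54386805, 958.0 kb with 103 probes, had a mean of -0.26 ± 0.03 (SD, n = 9) and ranged from -0.29 to -0.22. The longest other regions lay inside it, at 54123901 to 54332051 and 53994847 to 54181712, each with 19 probes. Their means over the family were -0.22 ± 0.08 and -0.21 ± 0.07 (SD, n = 9), and 7 animals were carriers at each. The ends of the loss of 103 probes are those of progeny 7, the animal of highest score. Windows called over the family lay there only between 53430657 and 53992339. A loss in all 9 animals is therefore not shown over its whole length. With normexp, the first stood at -0.08 in progeny 1 and the second at -0.01 in progeny 3, the animals of their highest scores. Because the loss on chromosome 10 and the loss of 103 probes on chromosome 14 were present in the whole family, they distinguish the family from the 1 reference animal. A higher copy number in that animal would give the same ratios, so loss means here only lower than the reference.

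Of the regions carried by exactly 1 parent, the one of highest score was a loss on chromosome 3 at 25417435 to 25432738, with 3 probes. The mother stood at -1.69 and the father at 0.04, and progeny 5, 6 and 7 carried it at -1.67 ± 0.04 (SD, n = 3) against 0.03 ± 0.06 (SD, n = 4) in the others. A gain on chromosome 8 at 102136827 to 102254870, 118.0 kb with 43 probes, had the same carriers. It stood at 0.26 in the mother, 0.006 in the father, 0.26 ± 0.010 (SD, n = 3) in carrier progeny and 0.007 ± 0.018 (SD, n = 4) in the others. The carriers of both regions are the animals with a raised chromosome X ratio and a low chromosome Y ratio. Both regions may therefore reflect no autosomal copy number. A loss on chromosome 3 at 40652115 to 40696375, with 7 probes, stood at -0.49 ± 0.22 (SD over probes) in the mother and 0.05 ± 0.18 in the father. Progeny 3, 4 and 5 stood at -0.84, -0.88 and -0.84, progeny 6 at -0.57, and the other 3 progeny at -0.03 ± 0.03 (SD, n = 3), so 4 of 7 progeny were carriers (exact 95% interval 18.4% to 90.1%). With normexp the value of progeny 5 in this region was -0.46.

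A region on chromosome 14 at 26698589 to 26758998, with 30 probes, took both signs within the family. The father stood at 0.19 and progeny 1 and 4 at 0.16 and 0.13. The mother stood at -0.21 and the other 5 progeny at -0.22 ± 0.02 (SD, n = 5). Calls of 10 or more probes at 26779391 to 26822021, 26809098 to 26944936 and 26740922 to 26758998 continued or overlapped it with the same 6 carriers. A gain on chromosome 11 at 3046630 to 3100205, with 24 probes and named after its values were seen, stood above 0 in all animals, from 0.07 in progeny 1 to 0.25 in progeny 6, with a mean of 0.15 ± 0.06 (SD, n = 9). Its parental values were 0.14 and 0.15. It was called only in progeny 6 and 7, and its median over probes in progeny 6 was 0.21. In every animal its mean was higher with the animal in Cy5 than in Cy3. These means were 0.34 and 0.18 in progeny 6 and 0.23 and 0.03 in progeny 5. The remaining named regions of this class had 3 probes each. On chromosome 13 at 95704529 to 95710693 all animals were above 0 (0.58 ± 0.16, SD, n = 9), but the median over the 3 probes in progeny 7 was 0.04 against a mean of 0.79. On chromosome 4 at 27362504 to 27365580 the father's mean of 0.80 became 0.04 without slide areas of high spread or without dim probes, and 0.07 with normexp. On chromosome 11 at 76354520 to 76359325 the mother's mean of -0.87 became 0.07 with normexp and 0.16 without dim probes.

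**Figure D2:**
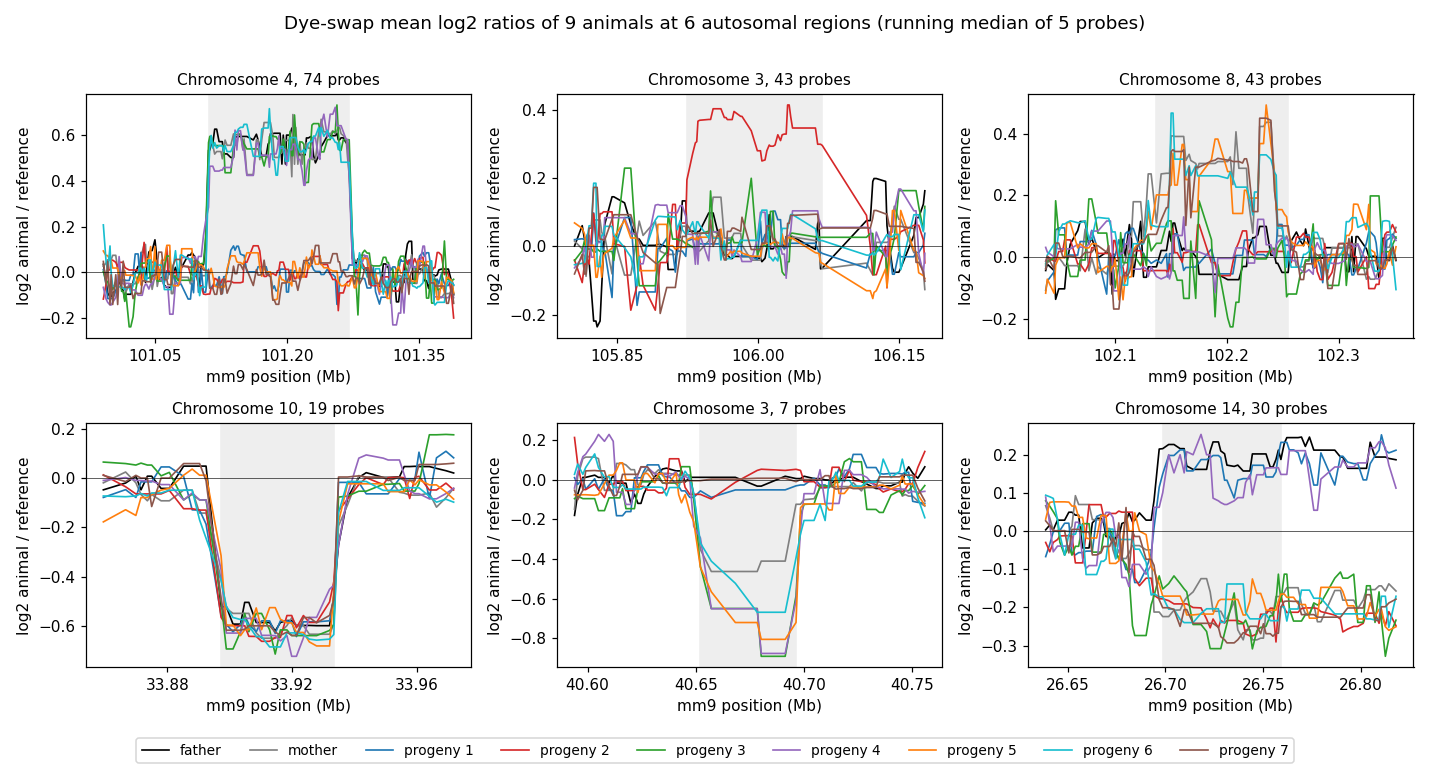
Dye-swap mean log2 ratio of animal to reference against position on mm9 in Mb, as a running median of 5 probes, with 1 line per animal and the region shaded. The chromosome 4 gain splits the family near 0.55 and 0, the chromosome 3 gain of 43 probes rises only in progeny 2, and the chromosome 10 loss is near -0.6 in all 9 animals.

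The second comparison asked which regions the progeny carried with no carrier parent. The region of highest score was a gain on chromosome 3 at 105924514 to 106068380, 143.9 kb with 43 probes, called in progeny 2 alone. Progeny 2 stood at 0.35 ± 0.07 (SD over probes), with 0.32 and 0.37 on its 2 arrays. The father and the mother stood at 0.02 ± 0.09 and 0.02 ± 0.09, and the other 6 progeny at 0.018 ± 0.013 (SD, n = 6). The score was 20.5, against 7.98 for the highest interval of 10 or more probes in the false-call scan and 18.9 for the highest of any size.

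Another 3 regions of 10 or more probes had no carrier parent and were singled out after their values were seen. A gain on chromosome 4 at 37161105 to 37199538, with 15 probes, stood at 0.27 ± 0.11 (SD over probes) in progeny 1, with 0.24 and 0.29 on its 2 arrays. Both parents were near 0 there (-0.04 and -0.01), and progeny 3 counted as a carrier at 0.17 ± 0.26. The region scored 10.2, against 7.98 for the highest interval of 10 or more probes in the false-call scan and 18.9 for any size. With normexp progeny 1 stood at 0.27. A gain on chromosome 1 at 71490446 to 71504895 in progeny 3 (0.29 ± 0.31) and a loss on chromosome 6 at 145174655 to 145195354 in progeny 4 (-0.25 ± 0.16), each with 11 probes, lay in the noisiest animals and scored 6.19 and 6.06. With normexp they stood at 0.11 and -0.08, and the mother stood at 0.11 ± 0.24 in the first. The false-call scan held 2 regions of this size.

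The other 9 named regions of this class had 3 probes each, and 8 of them were led by progeny 2. In 7 of these progeny 2 was lower, with means from -0.93 on chromosome 2 at 99829156 to 99837174 to -0.80 on chromosome 2 at 149717142 to 149721569. The other 5 lay on chromosomes 16, 18, 1, 8 and 10. Their medians over the probes lay between -0.18 and -0.04, so 1 probe carried each call. In 7 of the 8 named regions led by progeny 2 the most extreme probe lay within 200 position units of 1 point on a slide 19298 units wide. That point is the median position of 12 single low probes of progeny 2, described below. Some of the most extreme probes are among these 12, so this count is no separate support. Within that radius the SD of progeny 2 was 0.42 and 1.07 on its 2 arrays against at most 0.35 in other animals. Of all 161 regions of 3 or 4 probes led by progeny 2, 29 had their most extreme probe within 500 units of that point. Without slide areas of high spread the 7 lower means were between -0.10 and -0.02. A gain in progeny 6 on chromosome 5 at 40979234 to 40984495 stood at 1.15, with 0.21 and 2.08 on its 2 arrays, and at 0.16 without these areas. It stood at 1.18 with normexp and at 1.15 without dim probes. The median over its 3 probes was 0.17 with an SD of 1.71, so 1 probe carried this call too. A gain on chromosome 11 at 76357341 to 76361590 stood at 0.93 in progeny 2 with and without these areas. Progeny 6 was also a carrier at 0.49, and progeny 7 was called and stood at 0.40. The region overlaps the mother's loss at 76354520 to 76359325, so the 2 are not separate loci. No probe of it was left without dim probes, animals ranged there from -0.85 to 0.93, and with normexp progeny 2 stood at 0.01.

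Counted over all sizes, the scan gave 812 regions, of which 341 were higher and 471 lower than the reference. Progeny regions with no carrier parent numbered 569, and 226 regions were carried by exactly 1 parent. The false-call scan gave 705 regions, 490 of them with no carrier parent. Counts were lower and their ratio to the false-call scan was higher with normexp, at 112 regions against 28 and 68 with no carrier parent against 19, and at a score of 8, at 161 against 101 and 103 against 60. When each orientation was scanned alone there were 14 regions against 16, and 3 with no carrier parent against 14. Calls of 3 probes numbered 715, against 621 in the false-call scan, and calls of 10 or more probes 42, against 2. When the scan itself was held to 10 or more probes it gave 52 regions, against 27. The limit of 10 probes was chosen after the calls were seen. The 15 regions of 10 or more probes were 6 gains and 9 losses relative to the reference, and 4 had no carrier parent. Of the losses, 7 lay on chromosome 14, where they overlapped or continued the 2 loci described, so the losses are not 9 separate loci. Regions called in more than 1 animal numbered 49, against 8 in the false-call scan. Faults of a probe that animals share are largely removed from the false-call scan, so this compares only noise that differs between arrays. Of the regions carried by 1 parent, the father carried 120, of which 89 had no carrier progeny, and the mother carried 106, of which 49 had none. Only 5 of the father's and 21 of the mother's were called in 2 or more animals. No false-call count was made for regions carried by 1 parent, so these counts do not compare transmission from the father and the mother.

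**Figure D3:**
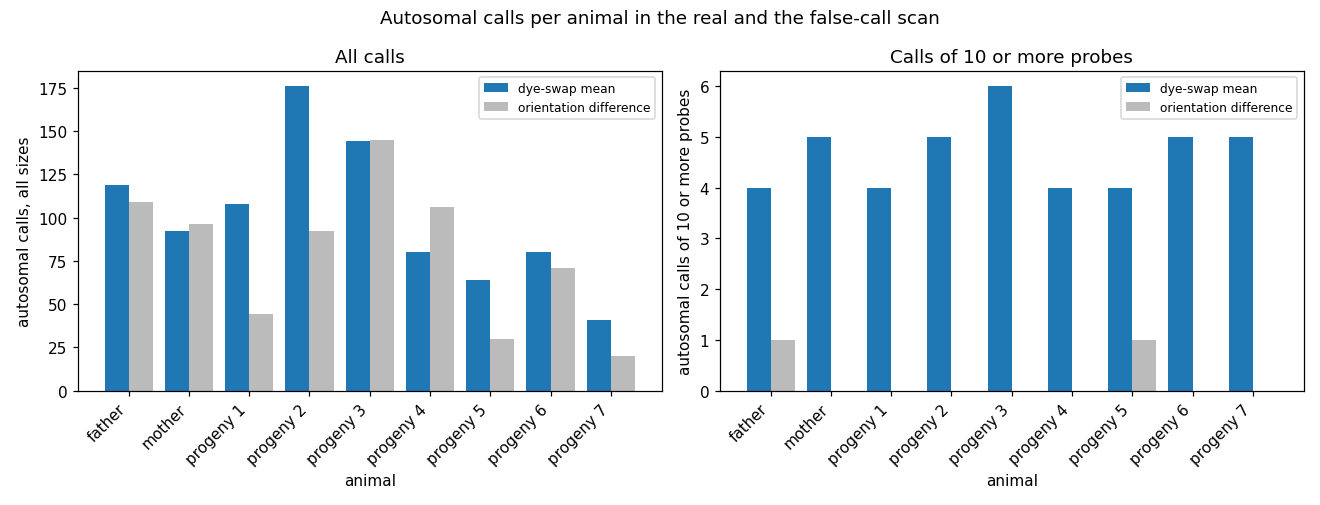
Number of autosomal calls per animal from the dye-swap mean (blue) and from the difference of the 2 dye orientations (grey), for calls of all sizes on the left and for calls of 10 or more probes on the right. Calls of all sizes number 108 against 44 in progeny 1, 176 against 92 in progeny 2, 64 against 30 in progeny 5 and 41 against 20 in progeny 7, while the other 5 animals have 80 to 144 against 71 to 145; calls of 10 or more probes number 4 to 6 per animal against 0 or 1.

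The third comparison set progeny beside parents. Progeny had 99 ± 47.2 calls per animal (SD, n = 7) and parents 105.5 ± 19.1 (SD, n = 2). The difference of -6.5 was within the spread between animals (exact two-sided permutation p = 0.889; the smallest p the 36 splits allow is 0.0278). Its sign turned under 5 alternatives, and it was not past the threshold in any. Parents were scanned on a day of their own, so scan day and generation cannot be told apart in this count. The false-call scan gave 109 calls in the father, 96 in the mother and 20 to 145 in the progeny. The calls compared here were not corrected for these, so the test does not show equal numbers of copy-number changes.

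In windows of 10 probes, 15 of 95054 windows differed from the reference over the family with limma (Benjamini-Hochberg adjusted), 7 higher and 8 lower, and all overlapped the regions on chromosomes 4, 10 and 14 already described. The 7 higher windows lay at 101115312 to 101268843 on chromosome 4, with means from 0.28 to 0.33 and an SD over animals of 0.26 to 0.32, because 5 animals carried the gain and 4 did not. The lowest window, on chromosome 10 at 33898897 to 33916306, stood at -0.62 ± 0.012 (SE, n = 9; limma adjusted p = 1.0e-25) and was lower in 9 of 9 animals. The 9 animals are 1 family measured against the same reference. This p treats related animals as independent replicates, so it does not extend beyond the family and this reference. With no minimum of the absolute log2, 3357 windows passed, 1076 of them higher. This count was 2023 without the mother and 1984, 1203, 1123 and 1135 without progeny 3, 4, 6 and 7, 1695 after subtraction of a running median, and 30206 and 34852 with the animal in Cy5 and in Cy3 only. Between progeny and parents, 4124 windows had an unadjusted limma p under 0.05, a smaller share of 95054 than the 0.05 chance gives. After adjustment limma called 0 windows, with a smallest adjusted p of 0.316. The simulation moved all 7 progeny, so it does not show whether this test would find a change in 1 of them. With scan day as a random block, which cannot separate day from generation because no progeny shared the parents' day, the count was also 0. With normexp it was 4, all in the chromosome 4 gain, which both parents and 3 of 7 progeny carried. Without the father it was 3, on chromosome 6 at 137378374 to 137397002, chromosome 2 at 158102873 to 158130624 and chromosome 12 at 77980004 to 77998089, where the mother alone stood at 0.34, 0.27 and 0.25 and the lone parent is assumed to vary like the progeny.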

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

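The tests below were chosen after the patterns were seen, except the test of a local defect on the slide, whose prediction was written down first. The use of the same slide distances against random noise was chosen after. Among the 7 progeny, 11 of 36 measures had an animal further from its nearest neighbour than Dixon's 95% limit, where chance gives about 1 in 20. Most of these measures are regions named because they were called in 1 animal, so the number is no test.

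The gain on chromosome 3 at 105924514 to 106068380 set progeny 2 apart at 0.35. Random noise was argued against by its score of 20.5, since the highest false-call score was 7.98 for 10 or more probes and 18.9 for any size. The region kept its mean of 0.35 without slide areas of high spread. The number of copies behind this level was not tested, because the response of these 43 probes to 1 copy is not known, and whether they lie in duplicated sequence was not examined. A gain in part of the tail cells, in a sequence with more copies in the reference, or a gain that arose in a parental germ line cell, may give it and stays open.

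Single probes that were below -1 on both arrays of progeny 2 and unremarkable in the other animals numbered 12, against 0 that were above 1 and 2 with opposite signs, while progeny 3 had 16, 10 and 40. Random noise of single spots was argued against by their place on the slide, where the median distance between the 12 spots was 128.4 position units against 6482 for random sets. A local defect on the slide met its prediction, at percentile 0 of 10000 random sets, and 9 of the 12 lay within 200 units of the median position of the 12. Such a defect may therefore account for those 9, although it has to be present on both arrays of this animal; the other 3 spots stay open, and no biological explanation was tested.

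The regions of 3 probes led by progeny 2 that stood apart had means of -0.93 and -0.80 on chromosome 2 and -0.93, -0.93, -0.88, -0.86 and -0.82 on chromosomes 16, 18, 1, 8 and 10, and the most extreme probe lay in the same patch in 7 of the 8 named regions of 3 probes led by progeny 2. Over all 161 regions of 3 or 4 probes led by progeny 2, 29 had it within 500 units. The gain on chromosome 5 set progeny 6 apart at a mean of 1.15, with a median over its 3 probes of 0.17. The gain on chromosome 1 at 71490446 to 71504895 set progeny 3 apart at 0.29. Progeny 3 also had 40 private probes beyond 1 with opposite signs on its 2 arrays, against at most 7 in the other animals.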

How the results depend on the processing

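Alternatives chosen after the data were seen were the minimum of 10 probes, the median rule, windows of 5 and 20 probes, leaving out progeny 3 and 4, and leaving out slide areas of high spread. Counts below are given as regions, progeny regions with no carrier parent and regions carried by 1 parent, with the first 2 counts of the false-call scan in parentheses where it was run. With normexp they were 112, 68 and 39 (28 and 19). Without dim probes they were 255, 161 and 87. At score threshold 5 they were 2664, 1930 and 706, and at threshold 8 they were 161, 103 and 50 (101 and 60). With a minimum of 5 probes they were 348, 238 and 101 (261 and 180), and with 10 probes 52, 32 and 15 (27 and 21). With the median rule they were 296, 214 and 75 (270 and 203). When each orientation was scanned alone they were 14, 3 and 7 (16 and 14). Leaving out progeny 3 and 4 gave 373 progeny regions with no carrier parent, from fewer animals. The cause of the other moves was not tested. A higher minimum number of probes leaves out short calls by construction, and most calls of the false-call scan had 3 probes. Without slide areas of high spread they were 708, 477 and 214 (642 and 440), and calls in progeny 2 went from 176 to 102. Other centring, the running median, the series table, each dye alone, an absolute log2 of 0.15 or 0.4, other carrier thresholds and an overlap of 25% left these counts within 1.5 times.

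Regions carried by all 9 animals numbered 2 except at an absolute log2 of 0.4 (7), at 0.15 and with the looser carrier threshold (3 each), and with the stricter carrier threshold (1). Without progeny 3 and 4, 3 regions were carried by all animals that were left.

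The difference in calls between progeny and parents turned to 2 with normexp, 7.93 with the animal in Cy3 only, 9 at an absolute log2 of 0.4, 2.64 with 10 probes and 4.43 with the median rule, and was 0 at threshold 8. The exact permutation p was 0.639 to 1 in these, so no direction was shown. The noise difference of the dye orientations kept its direction and stayed short of the threshold by median absolute deviation.

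Windows different over the family numbered 33 with 5 probes per window, 8 with 20 and 3357 with no minimum log2, and 13 to 16 when 1 animal was left out. With no minimum log2, leaving out 1 animal gave 1123 to 3329. Windows different between progeny and parents numbered 4 with normexp and 0 to 3 when 1 animal was left out, 3 without the father. The mother's chromosome X mean was 0.65 with normexp. Chromosome Y means with normexp were -0.60 in the mother and -0.73, -0.61 and -0.83 in progeny 5, 6 and 7. Of 231 alternative values of named regions 199 were unchanged by the rule for named regions, 30 moved and 2 turned. This rule is loose for 3 probes of large SD: the chromosome 5 gain of progeny 6 passed it at 0.16 against 1.15. The chromosome 3 gain of progeny 2 stood at 0.31 to 0.37 in all 8 alternatives of its values. Named regions with no probe left without dim probes have no value there. Both turned values were the mother's loss on chromosome 11 at 76354520, at 0.070 with normexp and 0.16 without dim probes. No paired analysis was possible because the father and the mother are 1 animal each and progeny numbers pair with no parent. Not run were minimum numbers of probes per gene and gene lists, since no gene is named on this build here. The array median of raw signal was as low as 2.54 times background, with 7722 spots of 1 array not well above it in red, which limits what a single probe shows.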

Other observations

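The test of carrier sets was chosen after the regions were seen, and the test of the number of animals per region was written down before its result. Regions carried by the mother and exactly by progeny 5, 6 and 7 recurred across the autosomes. Of the 106 regions with the mother as the only carrier parent, 21 were called in 2 or more animals, and 19 were left after overlapping regions were dropped. Of these 19, 8 had this set of carriers and lay on 7 chromosomes, 7 of them lower and 1 higher, and 6 had 3 probes. In 5 of the 8 the animal of highest score had a median over probes of -0.15 to -0.09 against a mean of -0.73 to -0.54, so 1 probe carried each. Besides those on chromosomes 3 and 8, they were lower regions at 123598779 to 123603094 and 109219280 to 109222308 on chromosome 5, at 35857910 to 35865189 on chromosome 9, at 112955152 to 112961441 on chromosome 11, at 104238274 to 104242812 on chromosome 6 and at 61798066 to 61804726 on chromosome 14. The mother stood between -0.72 and -0.30 in these 6 regions. These are the 4 animals with a raised chromosome X ratio and a low chromosome Y ratio.

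The explanation of maternal variants on different autosomes inherited independently was argued against, since each possible set of carrier progeny would be about equally frequent and 0.148 regions would be expected for a set named in advance, while 8 of the 19 regions called in 2 or more animals shared this set and no other set held more than 2. This set was picked because it recurred, so no p is given. In the false-call scan no region was called in more than 2 animals. This argued against random array noise for the regions on chromosomes 3 and 8, each called in 4 animals. The others were counted by their carriers, a looser measure. Carriers per region were not counted in the false-call scan, so this comparison does not cover them. Sequence shared by these probes with chromosome X (the higher region) or chromosome Y (the lower regions) is a candidate explanation that stays open. It was not tested, since no probe sequence or genome was used here, and under it these regions may reflect no autosomal copy number.

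A loss on chromosome 19 at 39810427 to 39879628, with 3 probes over 69.2 kb, had as carriers the mother and progeny 2, 3, 5, 6 and 7, the set seen at the region on chromosome 14 at 26698589 to 26758998. The mother stood at -0.41, and the father and progeny 1 and 4 at 0.02, -0.01 and -0.06.

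On unplaced contigs no animal stood apart. Means over 16 probes of a chromosome 1 contig lay between -0.020 and 0.033, and means over 20 probes of a chromosome 3 contig between -0.023 and 0.035.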
